A study of Homo sapiens with 4 samples.

How the data were processed

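RNA from 4 clones of A388, a human skin squamous cell carcinoma line that carries intact FAT1, was measured by bulk RNA sequencing. Per the labels, 2 clones had FAT1 knocked out with CRISPR (FAT1 KO) and 2 were FAT1 WT clones grown from single cells. RNA was extracted with an RNeasy micro kit and libraries were made with the Ovation SoLo system, per the labels' protocols. The submitters' processing notes name STAR, Picard and HTSeq and the build hg38 (GRCh38). Their roles, versions, gene annotation and counting strand are not given in the sources used here.

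The deposited table holds 1 signal value per gene and library, a read count that the authors scaled to a total near 20000000 per library and rounded up to whole numbers. This reading of the unit comes from the values: the 4 columns total between 20013012 and 20014175, and between 99.84% and 99.89% of non-zero values fall exactly on the rounded-up multiples of the worth of 1 read in that library. The multiples give 16838108 reads for FAT1 WT 1, 15818621 for FAT1 WT 2, 12800604 for FAT1 KO 1 and 12271364 for FAT1 KO 2. One read is thus worth 1.19, 1.26, 1.56 and 1.63 in the same order. The deposited values themselves are neither raw counts nor, after rounding up, whole multiples of 1 read, so the planned quasi-likelihood and negative binomial count tests were not run. Recovered reads were used for depth, counting intervals and 2 added alternatives. The table has 58051 genes and 0 columns of other samples.

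Samples were grouped by the genotype label. The replicate numbers only name the clones and pair nothing. Genes with a mean of at least 1 on a scale like CPM (each value over its library total) were kept, which left 17430. Log2(value + 1) was tested between the genotypes with limma 3.58.1 (lmFit and eBayes with an intensity trend, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. "Rose" and "fell" refer to genes past that threshold, and every adjusted p of a gene comes from this fit. Fold changes of low genes are understated on the log2(value + 1) scale. A second count asked also for an absolute log2 fold change of at least 1.

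The 39 gene lists, the tests and the rule for named genes were fixed before the data were examined. Lists were tested with camera in limma (preset correlation 0.01, adjusted over the lists), and again with the correlation estimated from the 4 libraries (statmod 1.5.0 installed), which leaves 2 residual degrees of freedom. The rule names FAT1, the genes of the study axis, the 12 largest rises and 12 largest falls among changed genes whose groups do not overlap and whose mean reaches 10 on that scale in the higher genotype, and up to 4 members of each list with the smallest p. Some genes that the rule names are not reported here. Other genes named in the text were chosen after their values were seen. The study axis list holds genes discussed in the published work on FAT1 loss, which may have been chosen on these samples.

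Where a genotype had 0 reads in both libraries, a fold is a lower bound computed against 3 reads per library. Where it had 1 to 3 reads in all, a printed ratio is that of the mean values, and its 95% counting interval comes from the recovered reads. Rounding up turns 1 read into a value of 2, so such ratios lie below those of the recovered reads. Intervals and bounds cover counting error only. Gene coordinates come from GENCODE 29 on GRCh38, matched by gene identifier, and 604 identifiers in the table had no match. Genes on chromosome Y and XIST were left out of the named results.

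Alternatives were other pseudocounts, filters, scalings (equal totals, median-of-ratios, TMM with 30% and 5% trims, quantile) and variance priors, and each library left out in turn. Precision weights (voom) on the recovered reads, and thinning to 12271364 reads per library, were added after seeing the data. The procedure was tested on simulated data for this comparison, 17385 genes at a dispersion of 0.05. There, 99.0% of genes changed 4-fold and 24.7% of genes changed 2-fold were called, as were 3 unchanged genes. The simulation changed only 200 genes, and its dispersion, the same for all genes, was not matched to these clones. Between real clones of a genotype the SD of log2 differences was 0.78 (WT) and 0.63 (KO). The simulated rates may therefore be too favourable for these data. Figures were drawn with matplotlib 3.10.9.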

Results

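The data are gene levels in 4 libraries, 2 from FAT1 WT clones and 2 from FAT1 KO clones of the A388 line. FAT1 is an atypical cadherin, and the study asked what its loss does to the epithelial and mesenchymal state of carcinoma cells. Recovered depth was 16838108 and 15818621 reads in FAT1 WT 1 and 2, and 12800604 and 12271364 in FAT1 KO 1 and 2. Mitochondrial transcripts took 4.96%, 2.76%, 5.01% and 5.31% of the signal in that order. Each library is a different clone, so the p-values measure the spread between these clones and cannot part the genotype from the history of the clones.

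FAT1 RNA (ENSG00000083857, chromosome 4, 186587783 to 186726722, GRCh38) did not separate the genotypes. Its values were 6042 and 2424 in FAT1 WT 1 and 2, and 6577 and 801 in FAT1 KO 1 and 2. The log2 fold change was -0.74 ± 1.05 (SE, n = 2 per genotype; limma adjusted p = 0.621). RNA level does not show whether a coding frame is intact, so FAT1 RNA leaves the genotype labels unchecked, and "FAT1 KO" below means the libraries labelled so. Of the other tested genes of the list, FJX1 (0.89 ± 0.44), FAT4 (0.62 ± 0.35) and FAT2 (0.03 ± 0.33) were not called, and 0 of 4 tested genes of the FAT and Dachsous list changed (0 adjusted over the list alone).

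In FAT1 KO, 21 of 35 epithelial adhesion genes, 14 of 18 inflammatory cytokine genes and 25 of 30 interferon-stimulated genes fell, and 17 of 21 NRF2 targets rose. These lists passed camera at the preset correlation, but with an estimated correlation camera passed 0 of 39 lists. There, adjusted p was 0.556 for the epithelial, cytokine and NRF2 lists and 0.604 for the interferon list. That second test uses only 2 residual degrees of freedom, so it has little power and speaks neither for nor against the lists. The preset of 0.01 is itself assumed. The estimates were -0.027 for the epithelial, 0.15 for the cytokine, 0.14 for the NRF2 and 0.56 for the interferon list. Of 17430 genes tested, 5189 changed, 2879 rising and 2310 falling, and 4809 changed at least 2-fold. The balance turned with the scaling, to 2488 rising and 2785 falling with TMM and 2534 and 2746 with median-of-ratios. Both FAT1 KO libraries lay above both FAT1 WT libraries for 6915 genes (39.7%) and below for 5382 (30.9%), where chance gives 16.7% in each direction. Pearson r across genes was 0.94 between the WT clones and 0.95 between the KO clones, against 0.60 to 0.62 between genotypes. There were 124 genes with a value of at least 200 in both KO libraries and at most 1 read in each WT library, and 97 the other way. The count of changed genes was 1226 without FAT1 WT 1, 2806 without FAT1 WT 2, 566 without FAT1 KO 1 and 567 without FAT1 KO 2, and 106 of the 142 named genes that were called lost the call in at least 1 of these fits.

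**Figure D1:**
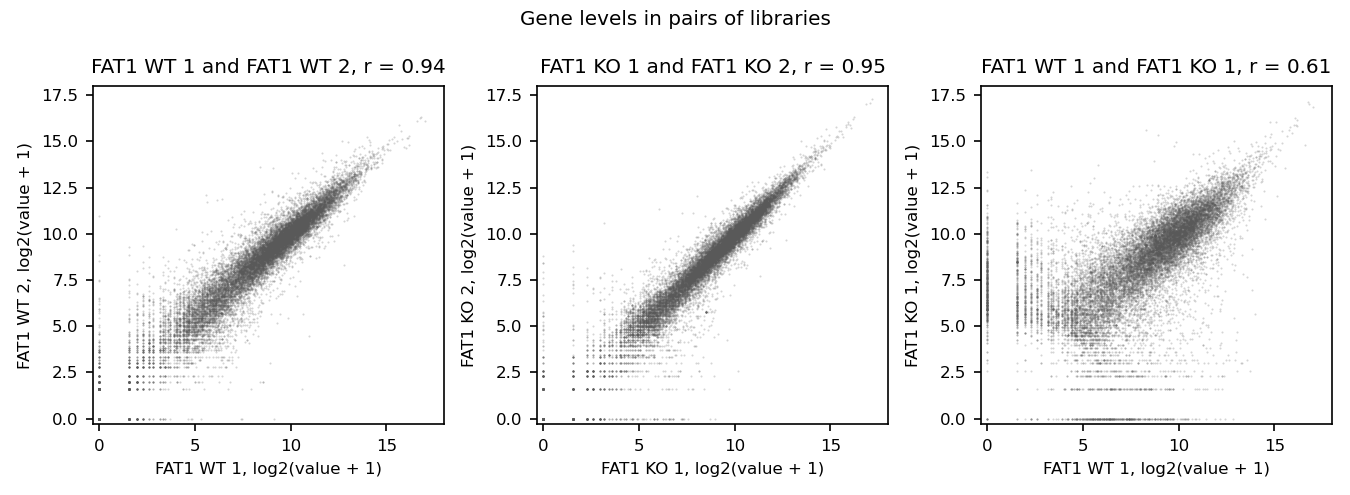
Log2(value + 1) of the 17430 tested genes, 1 point per gene, in 3 pairs of libraries. The WT clones (r = 0.94) and the KO clones (r = 0.95) follow the diagonal, while FAT1 WT 1 against FAT1 KO 1 (r = 0.61) has many genes along both axes.

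SOX2, a stem cell transcription factor, rose from 3 and 4 in the FAT1 WT clones to 5256 and 3912 in the FAT1 KO clones (log2 fold change 9.99 ± 0.39, adjusted p = 0.0015; chromosome 3, 181711924 to 181714436). The mesenchymal filament gene VIM rose from 5 and 12 to 172 and 472 (5.02 ± 0.73), and the EMT transcription factor ZEB1 from 6 and 14 to 166 and 87 (3.56 ± 0.66). Basal keratin KRT14 fell from 7479 and 7790 to 43 and 141 (-6.59 ± 0.57). E-cadherin (CDH1) fell 2.59-fold, from 9427 and 8602 to 2468 and 4492, whereas EPCAM rose 1.81-fold. The kinase gene CAMK2B had 0 and 3 in WT and 160 and 343 in KO, a ratio of 168 (95% counting interval 55.8 to 1685), while CAMK2A fell from 25 and 174 to 5 and 2. SRC fell 2.20-fold, from 3578 and 3056 to 1536 and 1480. The other 6 genes were not called: CAMK2D 0.95 ± 0.30, CAMK2G -0.49 ± 0.29, CD44 -0.27 ± 0.30, YAP1 0.47 ± 0.30, WWTR1 -0.69 ± 0.30 and EZH2 0.32 ± 0.28. Of the 15 study axis genes 5 rose and 4 fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.859), counts that are not independent evidence because the study may have chosen the genes on these samples.

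**Figure D2:**
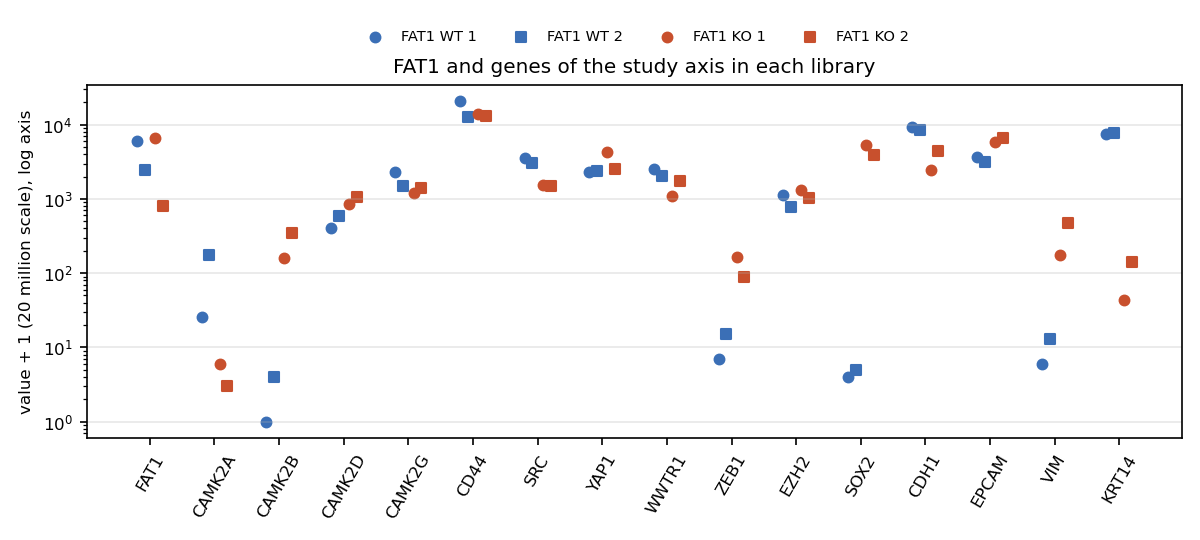
Value + 1 (signal, log axis) of FAT1 and the 15 study axis genes, 1 symbol per library, WT in blue and KO in orange. SOX2 sits at 3 and 4 in WT against 5256 and 3912 in KO, while FAT1 overlaps between genotypes.

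The largest rises were in genes nearly silent in the FAT1 WT clones. UCHL1, a neuronal ubiquitin hydrolase, had 0 and 2 in WT and 10297 and 11561 in KO (ratio 10929, 95% counting interval 3198 to 703997). EPDR1 reached 8722 and 7962, the neuronal nitric oxide synthase gene NOS1 5327 and 4939, and the proteoglycan GPC3 1904 and 7020. SLIT3, a guidance ligand, was at 0 in both WT libraries and at 5025 and 1780 in KO, at least 925-fold higher. ONECUT3 was at least 396-fold and LRP3 at least 339-fold higher. CES1 rose 3452-fold to 11405 and 33471, and GSTM3 and TMTC1 completed the 12 with C15orf59 and C15orf59-AS1. C15orf59 and C15orf59-AS1 lie on opposite strands and overlap from 73752317 to 73752747 on chromosome 15. Reads in that stretch cannot be assigned without the counting strand.

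Among the largest falls, THBD, thrombomodulin, fell from 7402 and 6843 to 0 and 2 (ratio 7122, 95% counting interval 1604 to 353095). GRHL2, a transcription factor of epithelial identity, fell from 4553 and 2826 to 0 and 2, and the EGFR ligand EREG from 4959 and 5486 to 4 and 0. LAD1 fell from 5422 and 4148 to 0 and 4 (ratio 2392, 95% counting interval 833 to 24868), ADGRF1 from 4887 and 2855 to 2 and 0 (3871, 878 to 193256), and LY6D had a log2 fold change of -10.81. The interferon-inducible genes IFI44 (3153 and 5177 to 4 and 0; ratio 2082, 717 to 21394) and PLSCR1 (at least 369-fold lower) were also among the 12. SLC43A3 (at least 758-fold lower) with RP11-872D17.8, and LY6D with RP11-706C16.8, may share reads.

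Of 35 epithelial adhesion and polarity genes 21 fell, 1 rose and 13 were not called (21 and 1 adjusted over the list alone). The splicing regulator ESRP1 fell 875-fold, from 5102 and 5403 to 7 and 5, and P-cadherin (CDH3) 467-fold. The list passed camera (adjusted p = 1.085e-09), with adjusted p = 0.556 with an estimated correlation. Keratinocyte differentiation genes fell in 14 of 23 and rose in 1 (14 and 2 adjusted over the list alone). The cornified envelope gene SPRR1A was at least 19.5-fold lower, SPRR1B fell from 339 and 152 to 2 and 2, and CALML5 from 265 and 2278 to 2 and 0, while FLG rose from 80 and 12 to 910 and 478. That list had camera adjusted p = 6.746e-05, and adjusted p = 0.556 with an estimated correlation. Of 11 stress and simple keratins 6 fell (7 adjusted over the list alone), among them KRT81 (856-fold), KRT16 (178-fold), KRT17 (128-fold) and KRT7 (69.1-fold). Its camera adjusted p was 0.00225, and adjusted p = 0.556 with an estimated correlation. Basal keratinocyte genes went both ways, 4 rising and 7 falling of 17 (4 and 8 adjusted over the list alone; camera adjusted p = 0.145). In that list KRT17 fell, while the hemidesmosome linker DST rose 4.68-fold and KRT5 rose 2.19-fold.

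Mesenchymal genes did not move as 1 group in the FAT1 KO libraries, with 7 rising and 7 falling of 21 (8 and 7 adjusted over the list alone; camera adjusted p = 0.441). THY1 was at least 296-fold higher, whereas the contractile genes TPM2 (755-fold) and MYL9 (at least 264-fold) were lower. Of 9 EMT transcription factors 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.623): FOXC2 rose from 2 and 2 to 46 and 51 (ratio 24.2, 95% counting interval 10.4 to 330), SNAI3 from 2 and 3 to 35 and 43 (15.6, 6.72 to 105), and SNAI1 fell 4.75-fold. Collagens rose in 10 of 17 and fell in 1 (10 and 1 adjusted over the list alone). COL3A1 and COL5A2 rose by 6.31 and 5.75 on the log2 scale, COL6A2 went from 0 and 2 to 860 and 719, and COL5A3 was at least 11.4-fold higher. The camera adjusted p was 0.00912, adjusted p = 0.750 with an estimated correlation, and adjusted p = 0.103 without FAT1 KO 1. On the Wnt response list 11 of 21 genes rose and 3 fell (11 and 3 adjusted over the list alone). That list also holds Wnt ligands and receptors, so its counts do not measure the response alone. The ligand WNT5A went from 2 and 3 to 1496 and 2026, NKD2 from 2 and 2 to 546 and 247, SFRP1 was at least 171-fold and LEF1 at least 70.4-fold higher. The camera adjusted p of 0.0459 became adjusted p = 0.751 with an estimated correlation, and was over 0.05 without FAT1 WT 1 (0.148), FAT1 WT 2 (0.0797) or FAT1 KO 1 (0.103).

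Matrix protease and plasminogen genes fell in 12 of 18 with 0 rising (13 and 1 adjusted over the list alone). Urokinase (PLAU) fell 892-fold, from 8528 and 4850 to 5 and 10, SERPINB2 872-fold, and MMP7 from 84 and 123 to 2 and 0. The list had camera adjusted p = 4.762e-05, and adjusted p = 0.556 with an estimated correlation. Integrins fell in 6 of 12 and rose in 2 (6 and 2 adjusted over the list alone): ITGB6 was at least 207-fold lower, ITGA5 fell 27.2-fold and ITGA6 2.36-fold, while ITGB8 rose 3.95-fold. The integrin camera adjusted p was 0.0307, with adjusted p = 0.751 with an estimated correlation, and it was over 0.05 without FAT1 WT 2 (0.0769) or FAT1 KO 2 (0.112).

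Inflammatory cytokine genes fell in 14 of 18 with 0 rising (16 falling adjusted over the list alone). CSF1 fell 575-fold and the NF-kB feedback genes TNFAIP3 and NFKBIA 99.6-fold and 7.30-fold, and CSF2 fell from 213 and 198 to 2 and 2. The list had camera adjusted p = 1.719e-09, and adjusted p = 0.556 with an estimated correlation. Interferon-stimulated genes fell in 25 of 30 with 0 rising (28 falling adjusted over the list alone), among them OASL (796-fold), IFI27 (139-fold), OAS3 (11.6-fold) and HERC5, which went from 1397 and 4078 to 0 and 2. The camera adjusted p was 1.693e-13, and adjusted p = 0.604 with an estimated correlation. MHC genes fell in 9 of 15 with 0 rising (11 falling adjusted over the list alone): the immunoproteasome subunit PSMB8 fell 361-fold, TAP2 7.52-fold, HLA-E 5.48-fold and NLRC5 3.10-fold. Its camera adjusted p was 7.109e-06, and adjusted p = 0.604 with an estimated correlation.

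EGFR ligand and MAPK feedback genes fell in 9 of 20 with 0 rising (9 falling adjusted over the list alone). HBEGF fell 97.0-fold, ERBB3 had a log2 fold change of -5.88 ± 0.29, and the ligand BTC was at least 34.4-fold lower. The list had camera adjusted p = 8.384e-05, and adjusted p = 0.604 with an estimated correlation. AP-1 and immediate early genes fell in 7 of 17 with 0 rising (7 falling adjusted over the list alone), including FOSB (5.63-fold), NR4A2 (6.16-fold), IER3 (4.66-fold) and KLF6 (3.03-fold). Here the camera adjusted p was 2.196e-04, and adjusted p = 0.604 with an estimated correlation.

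NRF2 targets, genes of the antioxidant and detoxification response, rose in 17 of 21 with 0 falling (18 rising adjusted over the list alone). AKR1B10 rose 531-fold, from 54 and 23 to 13483 and 27408. AKR1C2 rose 92.2-fold, AKR1C1 60.3-fold and AKR1C3 18.4-fold, though these near-identical paralogs may exchange reads. The list had camera adjusted p = 7.436e-08, and adjusted p = 0.556 with an estimated correlation.

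**Figure D3:**
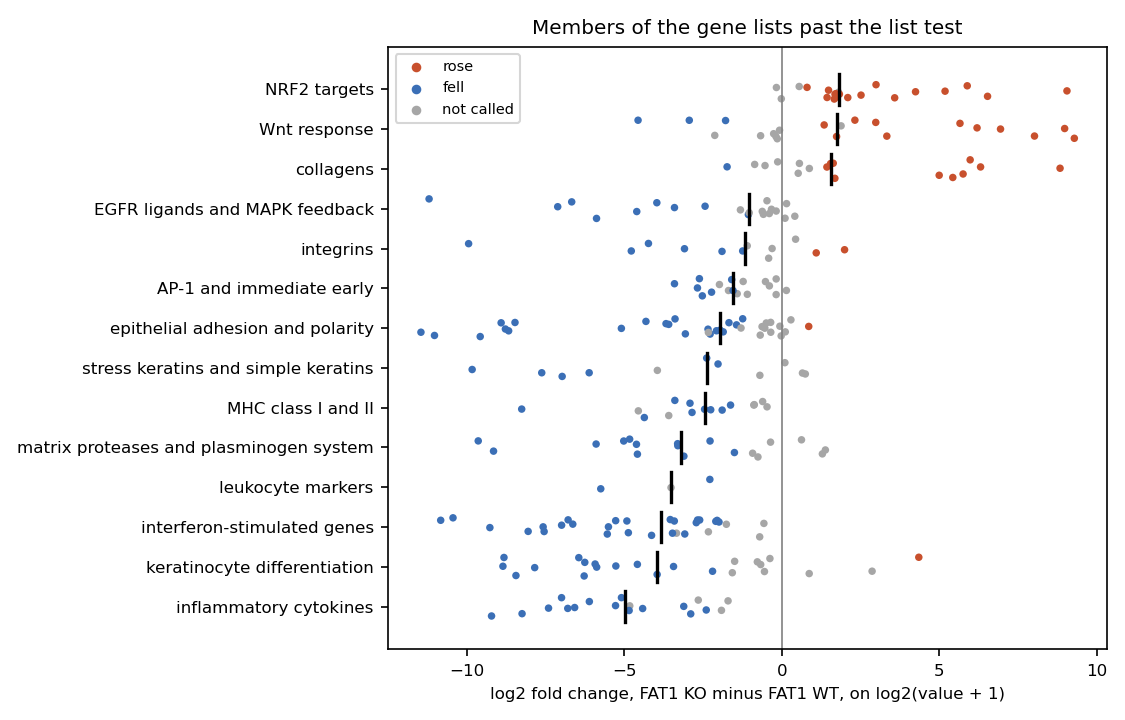
Log2 fold change (FAT1 KO minus FAT1 WT) of each tested member of the 14 lists past the camera threshold at the preset correlation, orange for rose, blue for fell and grey for not called, with the list median as a bar. Medians run from -4.96 for inflammatory cytokines to 1.80 for NRF2 targets.

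The Hippo and YAP lists, where FAT cadherins act upstream, did not pass camera. Of 22 YAP and TAZ targets 4 rose and 6 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.261): ANKRD1 rose 264-fold and IGFBP3 3.99-fold, CCDC80 fell (-3.67 ± 0.41), and NT5E fell from 661 and 949 to 0 and 2. Of 28 Hippo components 2 rose and 6 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.261), with the kinases STK3 (-2.32 ± 0.22) and TAOK3 (-2.75 ± 0.31) falling, VGLL3 falling from 364 and 344 to 2 and 0, and AMOT rising from 3 and 0 to 91 and 131. In PRC2, MTF2 fell 2.59-fold and PHF19 rose 1.99-fold, and 10 of 12 genes were not called (1 and 1 adjusted over the list alone; camera adjusted p = 0.859). Stemness genes rose in 4 and fell in 5 of 18 (4 and 5 adjusted over the list alone; camera adjusted p = 0.623), LRIG1 rising 48.7-fold and SOX9 and CD24 falling 91.3-fold and 9.97-fold. The stemness median was -0.17 and its mean 0.30, with camera direction down. SRC family and focal adhesion genes rose in 3 and fell in 5 of 20 (3 and 9 adjusted over the list alone; camera adjusted p = 0.0523), YES1 rising 9.62-fold, TNS1 4.77-fold and ZYX falling 13.4-fold.

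TGF-beta response genes rose in 11 and fell in 7 of 25 (12 and 7 adjusted over the list alone; camera adjusted p = 0.623): the pseudoreceptor BAMBI went from 2 and 2 to 2272 and 3306, TGIF1 rose 4.39-fold and TGFBI fell 97.0-fold. Notch genes rose in 4 and fell in 2 of 14 (4 and 2 adjusted over the list alone; camera adjusted p = 0.623), HEY1 rising 26.1-fold, HES5 at least 18.1-fold higher, and HES2 and NOTCH2 falling 4.85-fold and 2.98-fold. Planar cell polarity genes rose in 5 and fell in 5 of 14 (5 and 5 adjusted over the list alone), among them PTK7 (5.58-fold lower), FZD6 (2.93-fold lower), FZD3 (2.78-fold lower) and CELSR3 (7.47-fold higher). The polarity list's median was 0.71 and its mean 0.07, while camera gave the direction down (adjusted p = 0.859).

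Most proliferation genes were not called, 3 rising and 3 falling of 30 (1 and 0 adjusted over the list alone; camera adjusted p = 0.803). TYMS had the largest rise of the list, 33.0-fold from 936 and 849 to 31783 and 27209. CCNB2 and MCM5 rose 1.90-fold and 1.95-fold and CENPE fell 2.41-fold. Of 21 p53 targets 1 rose and 6 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.261), with CDKN1A, FAS, PLK3 and TNFRSF10B 2.19-fold, 13.2-fold, 5.66-fold and 4.36-fold lower. Of 25 hypoxia and glycolysis genes 3 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.292): ENO2 rose 5.67-fold and SLC2A1 2.09-fold, VEGFA fell 9.14-fold and CA9 fell from 375 and 392 to 2 and 0. In unfolded protein and amino acid stress, SLC7A11 rose 3.15-fold and SESN2 fell 2.46-fold, and 20 of 22 genes were not called (0 and 0 adjusted over the list alone; camera adjusted p = 0.859, with a median of 0.06, a mean of 0.08 and direction down). In cholesterol synthesis SQLE fell 2.08-fold, 0 rising and 2 falling of 24 (0 and 1 adjusted over the list alone; camera adjusted p = 0.623). Among 14 heat shock genes CRYAB rose 583-fold and HSP90AB1 and HSPA1A fell 2.90-fold and 3.51-fold (1 and 2 adjusted over the list alone; camera adjusted p = 0.859).

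Markers of other cell types were mostly low or moved apart. Fibroblast markers rose in 3 and fell in 2 of 5 (3 and 2 adjusted over the list alone; camera adjusted p = 0.623), with THY1 and COL3A1 up, LUM down from 220 and 178 to 4 and 0, and FAP at least 12.4-fold lower. Of 2 endothelial markers ERG fell from 55 and 26 to 2 and 0 and VWF was not called (1 and 1 adjusted over the list alone; camera adjusted p = 0.803). Of 3 leukocyte markers, the lysosomal gene CD68 fell 54.2-fold and CSF1R 5.71-fold (0 and 3 adjusted over the list alone); the camera adjusted p was 0.0219, and adjusted p = 0.604 with an estimated correlation. Of 3 melanocyte and neural markers TUBB3 fell 3.39-fold (0 and 1 adjusted over the list alone; camera adjusted p = 0.623). As signs of library composition, 0 of 13 mitochondrial transcripts (camera adjusted p = 0.332), 0 of 28 ribosomal protein genes (0.623) and 0 of 8 replication-dependent histone genes (0.623) changed in the limma fit, and 0 in each adjusted over the list alone. At an unadjusted p under 0.05 the whole fit had 7637 genes. Without FAT1 WT 1 the mitochondrial list passed camera (adjusted p = 0.00714).

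At the start of chromosome 18, all 11 expressed protein-coding genes between 596988 and 3459978 rose, a stretch picked out after its values were seen. TYMS and the overlapping ENOSF1 (5.03 ± 0.22) rose most among those named here, with YES1, NDC80 (2.13 ± 0.21), SMCHD1 (1.75 ± 0.22) and TGIF1. The median log2 fold change was 2.33 in the block and 0.59 in the 16 genes to its right, which ran from -0.41 to 7.95.

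**Figure D4:**
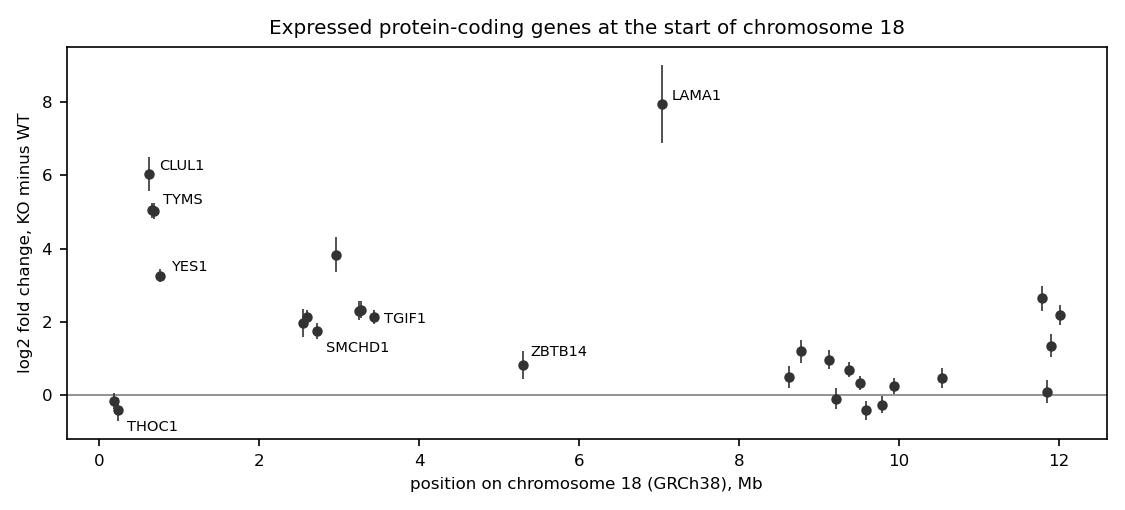
Log2 fold change (FAT1 KO minus FAT1 WT, ± SE) of each expressed protein-coding gene against its position in the first 12 Mb of chromosome 18. The 11 genes from 596988 to 3459978 lie at a median of 2.33 and the 2 genes to their left at -0.28.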

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

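Voom on the recovered reads and thinning to equal reads were chosen after seeing the data; the other alternatives were planned. The planned count tests were set for deposited counts or values that are whole multiples of 1 read, which rounding up prevents, so they were not run; voom was run on reads recovered by undoing the rounding. No paired analysis was possible because the replicate numbers follow sample order and link no FAT1 WT clone to a FAT1 KO clone. The count of 5189 changed genes, with all 4 libraries kept, ranged from 3489 without a filter to 5464 with quantile normalization, and was 5025 with voom and 5102 after thinning; 0 genes called both as planned and in an alternative changed sign. Without a filter 1537 genes fell, with 33418 genes tested. Leaving out 1 library, so that the lone clone is assumed to vary like the other genotype, gave 566 to 2806 changed genes (297 to 1893 rising, 215 to 913 falling), and the same 566 to 2806 at least 2-fold; fewer libraries leave 1 residual degree of freedom. The median of all genes shifted by -0.15 with median-of-ratios, -0.17 with TMM and -0.09 with quantile scaling, and the rising share went from 55.5% to 48.0%, 47.2% and 51.1%. The mean r between genotypes, 0.612, was 0.587 and 0.675 with pseudocounts of 0.5 and 5, 0.856 without a filter, 0.457 with a filter at 5, 0.596 with voom and 0.601 to 0.619 with a library left out.

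Of 142 called named genes, 142 kept their direction in all alternatives and 121 their call in all but the leave-one-out fits. Reversals were in genes not called: FAT2 was -0.12 with median-of-ratios and -0.14 with TMM, and -0.33 to 0.39 with a library left out, MT-CO1 was -0.064 with quantile scaling, and leaving out a library gave CD44 -0.63 to 0.087, PMEL -0.76 to 0.20 and FAT1 -2.25 to 0.78. The Wnt list lost its call with a pseudocount of 5 (adjusted p = 0.0517) and quantile scaling (0.0509), and ranged from 0.00463 to 0.148 with a library left out. Integrins lost it with a filter at 5 (0.162) and quantile scaling (0.0701), ranging from 0.0195 to 0.112, and collagens ranged from 0.00928 to 0.103. SRC family and focal adhesion genes passed without a filter (0.0282) and after thinning (0.0493), and mitochondrial transcripts ranged from 0.00714 to 0.720. With an estimated correlation all 14 called lists lost the call: adjusted p = 0.556 for epithelial adhesion, keratinocyte differentiation, keratins, matrix proteases, inflammatory cytokines and NRF2 targets, 0.604 for EGFR ligands, AP-1, interferon-stimulated, MHC and leukocyte genes, 0.750 for collagens, 0.751 for integrins and 0.751 for Wnt response. For epithelial adhesion, keratinocyte differentiation and leukocyte genes the estimated correlation (-0.027, -0.027 and -0.33) was below the preset 0.01. A higher correlation thus did not cost these lists the call, and that test uses only 2 residual degrees of freedom. The cause of the other list changes was not tested. Depth limits genes near 3 reads, worth 3.56 to 4.89 in value.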

Other observations

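The tests in this part were chosen after the results were seen, except that the bounds for JAK1's neighbours were written before their values were seen; the gene families were also chosen after seeing the data, and the criteria for the lineage and copy explanations were rewritten after their values were seen. Serpin clade B genes fell in 9 of 11 with 0 rising, at a median log2 fold change of -8.11. SERPINB4 was at least 272-fold and SERPINB11 at least 206-fold lower, and SERPINB1 went from 1022 and 2471 to 4 and 5. Kallikreins fell in 7 of 9, with KLK6 going from 2969 and 3995 to 30 and 9, and claudins fell in 6 of 12 and rose in 1, with CLDN7 going from 1650 and 3289 to 10 and 2. S100 genes fell in 7 of 15 and rose in 1: S100A14 went from 8069 and 8034 to 11 and 15, and S100A4 rose from 321 and 213 to 1146 and 1295. Mucins fell in 4 of 5 and rose in 1, MUC4 from 6216 and 6022 to 8 and 15. Camera over 20 families gave adjusted p = 3.820e-07 for serpins, 5.082e-04 for kallikreins, 0.00522 for claudins and 0.0141 for S100 genes and mucins, and with an estimated correlation adjusted p = 0.551 for serpins and 0.662 for the other 4.

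Positional identity genes moved in both directions, 5 rising and 9 falling of 29 HOX genes (camera adjusted p = 0.240). HOXC10 rose from 43 and 27 to 977 and 835 and HOXA13 from 50 and 38 to 396 and 649, while HOXA9 fell from 1022 and 1872 to 208 and 170. The cancer-testis gene MAGEA4 fell from 5305 and 7172 to 4 and 4. The 15 protocadherin genes that rose are all of the alpha cluster with nearly equal values, as are the 9 UDP-glucuronosyltransferases of the UGT1A locus; genes of each locus share exons, so each is 1 signal and not many. Fold changes of neighbouring genes correlated between genotypes (r = 0.21), between the WT clones (0.20) and between the KO clones (0.26), each at p = 9.99e-04, the smallest that 1000 shuffles can give. Windows of 11 genes beyond the 95th percentile of shuffles formed 3 segments between genotypes, around S100A7 (chromosome 1, 152032506 to 153646306), SERPINB8 (chromosome 18, 62523007 to 74523454) and KLK6 (chromosome 19, 50415799 to 52229533). These segments hold many of the S100, serpin clade B and kallikrein genes of the families above. The family results and the segments are therefore not separate evidence. The WT clones differed in 2 segments, 1 of them in the KLK6 stretch, with a peak window median of -1.79 in FAT1 WT 1 relative to FAT1 WT 2, against -2.76 between genotypes. The KO clones differed in 21 segments, many of them overlapping, which merge into 12 regions. Of the 21, 11 lie on chromosome X between 55143102 and 155943769 and merge into 3 regions, all lower in FAT1 KO 1 than in FAT1 KO 2, with peak window medians from -1.22 to -0.81.

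The fit called 5189 genes, and 566 to 2806 with 1 library left out. Depth and scaling as the whole cause are disfavoured by the 5102 genes called after thinning and the 5273 called with TMM. Of the 3 splits of the 4 libraries 1, the real one, called as many, and the highest other split called 0 (31 genes at an unadjusted p under 0.05 in limma). However, 3 splits are too few to reach a share of 0.05. The other splits also put the genotype difference into the spread within their groups, so their 0 gives no reference for chance. The pairs across genotypes hold at least 390 all-or-none genes, and the pairs within a genotype at most 14. These counts are part of the pattern to be explained, so they cannot decide its cause. Separate lineages behind the genotype labels are a candidate explanation. That hypothesis and loss of FAT1 as the whole cause (FAT1 log2 fold change -0.74) cannot be told apart here, because genotype and clone origin move together in 4 libraries.

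At the start of chromosome 18, all 11 expressed protein-coding genes between 596988 and 3459978 rose, by 1.75 to 6.03 on the log2 scale, including TYMS, YES1, NDC80, SMCHD1 and TGIF1. To the left, USP14 and THOC1 were not called (median -0.28), and the 16 genes to the right up to 12 Mb had a median of 0.59. Those 16 ran from -0.41 (PPP4R1) to 7.95 (LAMA1), and some of them rose, so the right bound of the block is uncertain. TYMS and ENOSF1 overlap, but the 9 genes that overlap no other protein-coding gene had a median of 2.31. That argues against reads shared between protein-coding genes as the whole cause. Overlap with genes of other types was not checked. A gain of gene copies may explain the block. Its median of 2.33 lies barely above the highest of 10362 other windows of that size (2.31), yet the block was bounded after its values were seen. The scan with fixed windows, whose values have the median of all scanned genes subtracted, did not find it (2.28 against a shuffled limit of 2.55). The 16 other tested genes inside the block, looked at after that result, were also all at least 2-fold higher. They are of any type and were not checked for overlap with the 11 genes. Without the counting strand they may share reads with those, so they are not separate evidence. No DNA was analysed here, so copy gain and regulation cannot be told apart.

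JAK1, the kinase shared by interferon receptors, fell from 3615 and 3892 to 99 and 126 (-5.06 ± 0.26) beside 25 of 30 interferon-stimulated genes. After thinning to equal reads the same 25 fell, which argues against depth. The 10 nearest expressed genes had a median of -0.96. That lies between the -1.5 and -0.7 set beforehand as bounds for and against loss of a segment. The 10 genes ran from -2.30 ± 0.24 (PGM1) to 0.01 ± 0.24 (adjacent RAVER2), each above JAK1. These values argue against loss of a segment spanning all 10 as the whole cause of the fall of JAK1. However, PGM1, AK4, LEPROT, MIER1, SLC35D1 and SERBP1 fell, while ITGB3BP, EFCAB7, CACHD1 and RAVER2 were not called. Over all 17430 genes tested, 2310 fell. Loss of a smaller segment, or a part of segment loss in the fall of JAK1, stays open. IFNGR1, IRF1, IRF9 and MB21D1 fell too, while IFNAR1, IFNAR2, JAK2, TYK2 and STAT2 were not called. Low JAK1 (-5.06) may contribute to the low interferon-stimulated genes, but JAK1 and genotype move together in the 4 libraries and cannot be told apart.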
